A study of Glycine max with 24 samples.

How the data were processed

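RNA was sequenced from detached trifoliolate leaves of soybean (Glycine max) in 24 libraries, which the labels place in 8 groups of 3. The groups combine 4 lines with 2 treatments. LD and LDX are the parents of a population of recombinant inbred lines (RILs), which are lines made nearly homozygous by repeated selfing after a cross, and R-11268 and R-11272 are 2 lines of that population. Leaves of 5 plants aged 3 weeks (16 h photoperiod) were pooled per genotype, cut into slices and shared out between 2 dishes. For 30 min 1 dish held 5 ml of a solution with 1 µM flg22 and 50 µg of crab shell chitin, and the other held a mock solution of water and DMSO. Flg22 is a peptide of bacterial flagellin and chitin a polymer of fungal cell walls. Plants perceive both as microbe-associated molecular patterns (MAMPs). Libraries were made with a TruSeq kit, per the labels.

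The deposited table holds estimated counts for 41743 transcripts of 41550 loci in 24 columns, and the authors' step that made these estimated counts is not given in the sources used here. Bowtie 0.12.7, TopHat 1.4.1 and Cufflinks 1.1.0 are named in the submitters' processing notes. The genome build, the annotation release and the handling of reads that match several genes are not given in the sources used here. Column totals differ like library sizes, from 9780810 to 20827163, and values need not be whole, so the values were read as estimated counts, not as FPKM. The column names end in C or P and a number. C was read as control, and P, which no label explains, as the only other treatment, MAMP. No other column of per-sample values was present.

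The deposited values are not independent library measurements. In each line the ratio of the MAMP to the control value was identical in replicates 1, 2 and 3, once divided by its median over transcripts in that replicate. The 99th percentile of its SD over the 3 replicates was at most 2e-09 on the log2 scale, and 100% of transcripts with all 6 values above 0.1 had an SD under 0.001. Totals over the 3 libraries of a group were whole numbers, within a tolerance of 0.02, for 20.7% to 33.9% of totals between 100 and 1000, against 3.93% to 4.14% of single values in the same range. The table thus has the form of fitted values from a model with a line by treatment term and a line by replicate term. Most group totals are not whole, so they are not taken as exact read counts. The scatter of a MAMP effect between replicates is absent from the table. The replicate number was taken to tie a control and a MAMP library of 1 plant pool. Deviations from group means correlated across transcripts at 0.987 or more for libraries with the same number in a line. For libraries with other numbers the correlation was 0.809 or less. Because the values are fitted, this pairing cannot be separated from the authors' model.

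Values were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Low transcripts were removed with filterByExpr (minimum count 10, minimum total count 15), which left 33214 transcripts. Libraries were scaled with TMM, and all 24 libraries entered 1 quasi-likelihood fit with 8 group means, no block and 16 residual degrees of freedom. The control and MAMP deviations of a pool nearly coincide, so each pool enters the residual spread with both of its libraries. The 16 degrees of freedom thus overstate the independent ones, and p-values, above all of line differences, may be too small. Transcripts were called at a Benjamini-Hochberg adjusted p under 0.05. The spread in this fit comes from differences between plant pools as the deposited fitted values hold them. For scarce transcripts it lies far below counting error. Squared deviations of libraries from their share of a group total were set against counting expectation. Their median ratio was 0.000827 to 0.00507 at group totals of 0.5 to 5.5, and 0.0829 to 0.246 at 5.5 to 30. P-values of scarce transcripts may thus be too small. For abundant ones, a MAMP effect was tested against more variation than a paired test on independent values would use. No test could measure its own replicate error. Line differences measured in control and in MAMP libraries share the same pools and are not independent of each other, so line differences rest on 12 pools, and sums over each pool are given beside them.

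The comparisons, their tests, the first set of alternatives and the rule for named genes were set before the data were examined; what was added later is named below. The rule took up to 14 rising and 8 falling genes for the mean MAMP response, 8 in each line for the line differences and up to 5 in each direction for response differences. They were ranked by fold (response differences by adjusted p) among calls that agreed in direction over the 4 lines, or over both treatments with control libraries that did not overlap. The rule fell back to 2 identifiers in each direction where genes have no names. None of the 41743 identifiers (0 matched) occurs in the table of names at hand, and the deposited table pairs no identifier with a name, so this fallback was used. For the same reason 31 gene lists set in advance (MAMP signalling, defence, leaf function and markers of other tissues) could not be tested. Chromosome and order along it were read from the identifiers, which carry the chromosome number and a rising number along that chromosome; 41603 transcripts lie on 20 chromosomes and 140 on scaffolds.

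To place the RILs between their parents, transcripts called between LD and LDX in control libraries, with an absolute log2 fold of 1 or more, were kept where the MAMP libraries differed the same way by at least 0.5 on the log2 scale. The position of each RIL in the MAMP libraries was then computed on log2(CPM + 1), with LDX at 0 and LD at 1. Positions under 0.25 were called LDX-like, over 0.75 LD-like, below -0.5 or over 1.5 outside, and the remaining ones between. For the share of neighbours of the same class, only LD-like and LDX-like loci were kept. A neighbour is thus the next such locus on the chromosome, past any between or outside transcripts. That share was compared with 100000 shuffles of these classes within chromosomes (10000 for alternatives, 1-sided permutation test). Intervals are 95% exact binomial, and the floor for a group at 0 is 3 counts over its 3 libraries. Both cover counting error only, since reads carry no molecular identifiers.

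The fit was tested on simulated data. For the mean MAMP response 33214 transcripts were tested, but changes were planted only in a small sample above a minimum mean count. Recovery was thus not measured for scarce transcripts. In simulated independent libraries the fit recovered 90% of planted changes of 1 on the log2 scale and 100% of those of 2. There 4.04% of its calls were false. With differences between plant pools added, it recovered 86% and 100% with 0% false calls (edgeR), and on fitted values built from these libraries as above 88% and 100% with 1.57% false calls. With no treatment effect it made 0 calls, both on simulated libraries and on fitted values built from them as above. Without a difference of responses between lines, the F test and both pairwise tests also made 0 calls (edgeR), while fitting raised the transcripts at an unadjusted p under 0.05 from 69 to 518 in the F test, from 214 to 720 for LD minus LDX and from 192 to 722 for R-11268 minus R-11272. The simulated fit had no added step that drew pools of scarce transcripts together. Its 0 calls thus do not show that tests of scarce transcripts are safe in the deposited table. A fit with the replicate number as a block made 0 calls on simulated libraries but 14031 on such fitted values, so blocked results of MAMP effects are void here. Alternatives were DESeq2 1.42.0, its size factors, 2 other filters, the replicate block, fits on the compared groups alone and leaving out each library. Further ones were added after seeing the data: a minimum mean of 100 estimated counts, leaving out 3 plant pools, limma 3.58.1 with the 4 lines as replicates, and sums over each pool. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.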

Results

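Leaf transcripts were measured in 4 soybean lines, the parents LD and LDX and their recombinant inbred descendants R-11268 and R-11272, after 30 min with a mixture of the bacterial peptide flg22 and chitin (MAMP) or with a mock solution (control). Each of the 8 groups had 3 libraries. They were read as 3 pools of 5 plants per line, each giving a control and a MAMP library. Which libraries share a pool was read from the replicate number. Totals ranged from 9780810 estimated counts (LD control replicate 2) to 20827163 (R-11272 MAMP replicate 2). Group totals over 3 libraries were 43455833 in LD control, 45518526 in LD MAMP, 48515348 in LDX control, 50887029 in LDX MAMP, 49472692 in R-11268 control, 51248626 in R-11268 MAMP, 47985291 in R-11272 control and 52728175 in R-11272 MAMP. Transcripts above 1 estimated count numbered 36729 in the shallowest library and 38955 in the deepest. The p-values below measure spread between pools as the fitted values hold it, and that of scarce transcripts lies below counting error. Their p-values and SDs may thus be too small. The deposited values hold no separate replicate error of a MAMP effect.

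The first question was what the MAMP mixture did to leaf transcripts. Within 30 min the change was mostly upward. Averaged over the 4 lines, 2574 transcripts rose and 664 fell among 33214 tested (3238 calls). Of the calls, 1523 rose by 2-fold or more and 330 by 8-fold or more, against 54 that fell by 2-fold or more and 0 that fell by 8-fold. The rise was shared: 2508 of the 2574 rising transcripts had a positive fitted response in all 4 lines, with median log2 responses of 1.44 in LD, 1.18 in LDX, 1.13 in R-11268 and 1.26 in R-11272. The falling ones moved less, with medians of -0.47 in LD, -0.51 in LDX, -0.45 in R-11268 and -0.53 in R-11272, and 568 of 664 were negative in all lines. Both sets were chosen on the mean of these same responses, so the shared signs and the medians are partly built in.

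The largest fitted rise was that of Glyma10g37910.1, a transcript of chromosome 10, at 6.76 on the log2 scale (edgeR adjusted p = 1.29e-08, positive in 4 of 4 lines). It was nearly absent before treatment. The 12 control libraries together held 3.98 estimated counts and the 12 MAMP libraries 261.5, a ratio of 64.5 with a counting interval of 24.8 to 238. Glyma10g03970.1, also on chromosome 10, reached 2005 estimated counts in the 12 MAMP libraries, 19.5 times the control level (16 to 24.1), with a fitted mean log2 response of 6.71 (edgeR adjusted p = 0.000133). Its 4 line responses spread widely, from 10.60 in LD, where the controls were at 0, to 2.75 in R-11272, with an SD of 3.85 over the 4 lines. Pools within a line also differed widely for it, with 18.4 ± 28.1 CPM in LDX MAMP and 15.5 ± 23 CPM in R-11272 MAMP libraries (SD, n = 3 pools), so single pools carry much of the total. Glyma02g37360.1 showed the strongest fall that met the rule. It went from 69.1 to 10.81 estimated counts over 12 libraries each, 6.51-fold lower (3.36 to 13.4), at -2.64 on the log2 scale (edgeR adjusted p = 0.0159, negative in 4 of 4 lines). Glyma13g43250.1 went from 69.1 to 28.83 estimated counts, a fitted log2 response of -2.15 (edgeR adjusted p = 0.0495), and 25 of 31 alternatives ended that call. These identifiers have no gene names in the sources used here.

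The calls came from edgeR's quasi-likelihood test against the spread between pools. With the 4 lines as replicates, which uses only the consistency of the response from line to line, limma called 2731 transcripts higher and 932 lower, and 2203 of the 2574 rising but 256 of the 664 falling transcripts were among them. Without 3 pools that stand apart from the others, described at the end, 6093 transcripts were called (3400 higher, 2693 lower). The fit with a replicate block gave 18199 calls (42% higher) and is void for these fitted values.

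Each line responded in the same sense. In LD 1454 transcripts rose and 97 fell, in LDX 1151 rose and 103 fell, in R-11268 1048 rose and 77 fell, and in R-11272 1294 rose and 135 fell. Rises of 8-fold or more numbered 374 in LD, 279 in LDX, 165 in R-11268 and 249 in R-11272. A core of 804 transcripts was called higher in each of the 4 lines, against 0.0619 expected if the 4 lists were independent, while 1 transcript was called lower in each. The lists share 1 fit and 1 spread per transcript, so they are not independent and part of this excess is built in. Across the 33214 tested transcripts, which are not independent replicates, the log2 responses of LD and LDX correlated at 0.768 (Pearson) and those of R-11268 and R-11272 at 0.688. The remaining line pairs lay between 0.56 and 0.708. By rank (Spearman) the agreement was weaker, at 0.479 for LD and LDX, 0.416 for the RILs and 0.288 to 0.499 for the rest. The number of calls in a line depends on the libraries in the fit, for a cause that was not tested. Fits on the 6 libraries of a line alone, with their own filter and scaling, called 155 transcripts in LDX, 2546 in R-11268 and 685 in R-11272. The main fit gives all lines 1 spread per transcript, though their scatter differed. At group totals of 300 to 1000 the median squared deviation over counting expectation was 3.36 in both R-11268 groups. It was 7.29 to 8.65 in LD, 19.5 to 30.3 in R-11272 and 31.2 to 34.9 in LDX. Alone, the line with the least scatter gained calls and those with the most lost them. Without the 3 pools apart 2132 rose and 314 fell in LD, 1863 and 302 in LDX, 2131 and 612 in R-11268 and 2178 and 979 in R-11272, so more falls were called in every line, and the void blocked fits called 14644, 13640, 11327 and 15709 in that order.

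**Figure D1:**
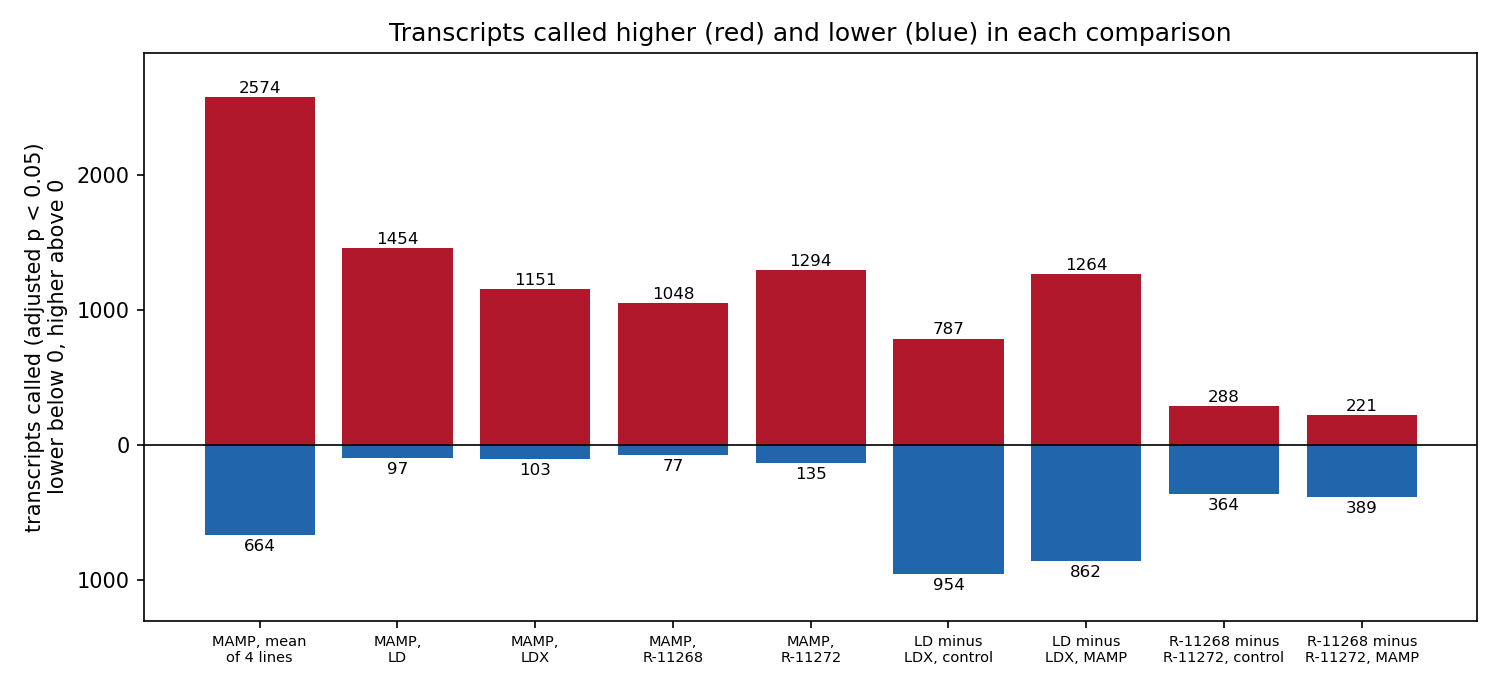
Number of transcripts called at an edgeR adjusted p under 0.05 (vertical axis) in each comparison (horizontal axis), with those higher drawn above 0 and those lower drawn below 0; groups hold 3 libraries each. The MAMP comparisons lean upward, with 2574 higher against 664 lower for the mean of the 4 lines, while the line comparisons are closer to balanced, with 787 and 954 for LD against LDX in control libraries.

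The next question was whether the lines responded differently. An F test over the 4 lines called 49 transcripts. Of these, 16 rose in all 4 lines to different extents, and in 11 of the 16 the smallest rise was in R-11268. The other 33 had responses of both signs or of 0. The response was highest in R-11272 for 27 of the 49 and lowest in R-11268 for 21. A direct test of LD minus LDX called 4 transcripts, all with a larger rise in LD, and that of R-11268 minus R-11272 called 11, of which 10 were more positive in R-11272.

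Glyma17g05240.1 on chromosome 17 rose by 4.97 on the log2 scale in LD and 4.64 in R-11272, but by 2.58 in LDX and 2.55 in R-11268. The difference between the parents was 2.39 (edgeR adjusted p = 0.0328). The lines with the larger rise started lower. Control levels were 0.202 ± 0.0355 CPM in LD and 0.176 ± 0.0158 CPM in R-11272, against 0.656 ± 0.134 CPM in LDX and 0.894 ± 0.121 CPM in R-11268 (SD, n = 3 pools), and MAMP levels reached 6.52 ± 1.65, 4.52 ± 0.187, 3.96 ± 0.958 and 5.28 ± 0.635 CPM in that order. The control level itself was called different between LD and LDX (log2 -1.67, edgeR adjusted p = 0.0158) and between R-11268 and R-11272 (2.31, 9.61e-05). The control groups of LD and R-11272 held only 8.994 and 6.993 estimated counts over 3 libraries. Spread at such totals lies below counting error in these fitted values, so those SDs and the p-values may be too small. Glyma08g07080.1 on chromosome 8 rose by 6.51 in LD and by 3.31 in LDX, 3.41 in R-11268 and 3.05 in R-11272, a parental difference of 3.20 (edgeR adjusted p = 0.0328). Its LD controls held 2.998 estimated counts over 3 libraries.

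Between the RILs the directions were opposite. Glyma03g41580.1 on chromosome 3 fell in R-11268, from 32.77 to 4.964 estimated counts over 3 libraries, and rose in R-11272, from 23.97 to 87.89. That is a difference of -4.30 on the log2 scale (edgeR adjusted p = 0.000156). Glyma20g25110.1 on chromosome 20 went from 1.56 ± 0.143 to 0.686 ± 0.0576 CPM in R-11268 and from 0.74 ± 0.00898 to 1.87 ± 0.00484 CPM in R-11272 (SD, n = 3 pools), a difference of -2.51 (edgeR adjusted p = 0.000156). Its R-11272 groups held 33.91 and 96.75 estimated counts, and counting error alone exceeds these R-11272 SDs. They are SDs of fitted values and do not measure how pools vary, and the p-value may be too small. Glyma14g21580.1 on chromosome 14 was the exception in direction. Its log2 response was 1.41 in R-11268 and -1.43 in R-11272, a difference of 2.84 (edgeR adjusted p = 0.0407). All alternatives used the same fitted values, so they do not test the small spread of these transcripts. The calls for Glyma03g41580.1 and Glyma20g25110.1 held in all 19 alternatives that tested them, the void blocked fit among these, while the filter at a mean of 100 removed both. By contrast, 12 of 19 ended the parental call for Glyma17g05240.1, 13 of 19 that for Glyma08g07080.1 and 13 of 19 that for Glyma14g21580.1. Leaving out any of 11 of the 12 parental libraries (all but LD MAMP replicate 1) brought the 4 parental calls to 0 or 1, and leaving out any of 10 of the 12 RIL libraries (all but R-11268 control replicate 3 and R-11272 MAMP replicate 1) brought the 11 RIL calls to between 3 and 7. The 49 calls of the F test fell to 32 without LD control replicate 1, 29 without LD control replicate 3 and 26 without R-11272 control replicate 2. Without the 3 pools apart the counts were 142 for the F test, 0 for the parents (edgeR) and 31 for the RILs, and the void blocked fits gave 17862, 8682 and 10250.

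**Figure D2:**
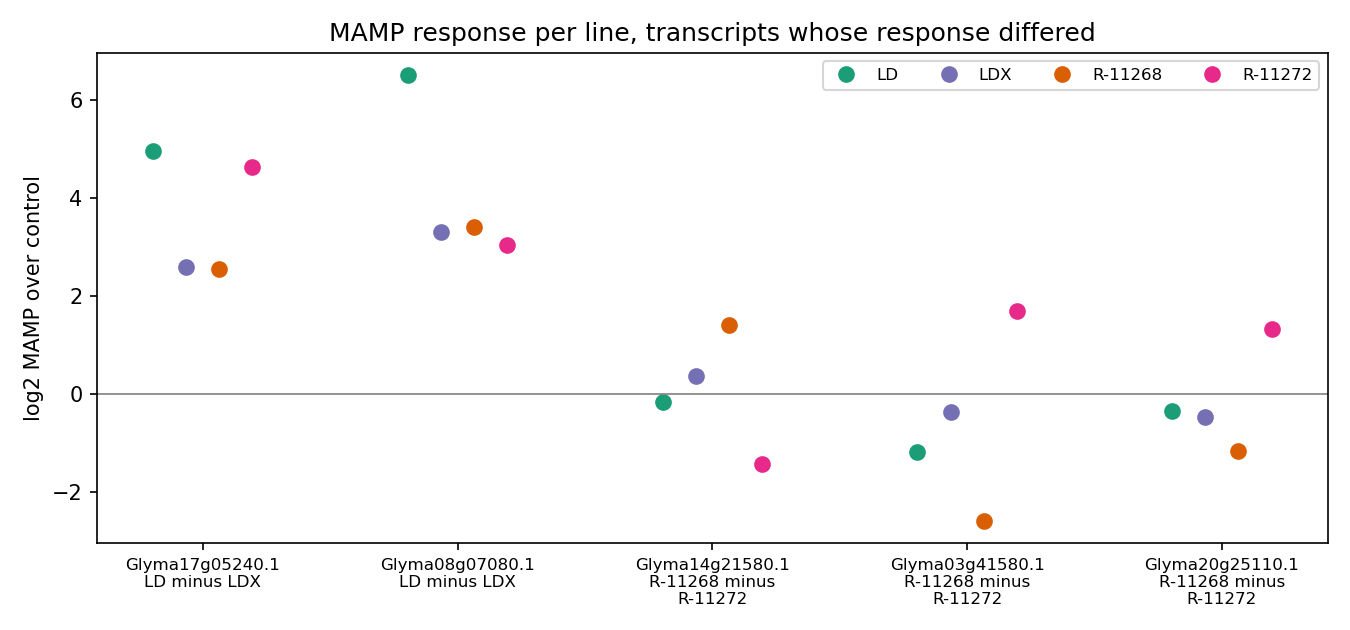
Fitted log2 ratio of MAMP over control (vertical axis) in each of the 4 lines (colours, 1 point per line, from 3 libraries per treatment) for the 5 transcripts named for a difference in response (horizontal axis). Glyma17g05240.1 forms pairs, with LD and R-11272 at 4.97 and 4.64 and LDX and R-11268 at 2.58 and 2.55.

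The parents differed in expression without treatment. In control libraries 787 transcripts were higher in LD and 954 higher in LDX (1741 calls), and 188 and 164 of them by 8-fold or more. Glyma02g03230.1 on chromosome 2 was among the most divergent. It held 4400 ± 96.6 CPM in LD and 0.717 ± 0.212 CPM in LDX (SD, n = 3), a ratio of 5900 with a counting interval of 4290 to 8320 (edgeR adjusted p = 4.86e-10). Glyma18g43980.1 had 979 estimated counts in the LD controls and 0 in those of LDX, at least 366-fold higher in LD against a floor of 3 counts over the group (edgeR adjusted p = 0.0284; 7 of 14 alternatives ended this call). In the other direction Glyma19g11560.1 had 1092 estimated counts in LDX and 0 in LD, at least 324-fold lower in LD (edgeR adjusted p = 6.39e-07), and Glyma12g18710.1 had 693 in LDX and 0.958 in LD, a ratio of 645 with a wide counting interval of 111 to 24400 (edgeR adjusted p = 5.92e-06). The 3 control libraries of each line did not overlap for these 4 transcripts, as the rule required; 10% of transcripts do so by chance.

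In MAMP libraries 1264 transcripts were higher in LD and 862 higher in LDX (2126 calls), and 617 of the 787 and 530 of the 954 control calls were among them in the same direction; these comparisons share their plant pools. The parents' calls were not spread evenly over chromosomes. On chromosome 18, 129 of 1858 tested transcripts (6.94%) were called with a 2-fold difference or more in control libraries, against 3.71% of all 33123 transcripts on chromosomes and 2.19% on chromosome 9. The calls of chromosome 18 went both ways, with 72 higher in LD and 57 higher in LDX (55.8% higher in LD). The number and balance of parental calls depended on the pools. Without the 3 pools apart there were 4416 calls in control libraries (2602 higher in LD, 1814 in LDX) and 4764 in MAMP libraries, and with only the 6 libraries compared there were 382 (215 higher in LD, 167 in LDX) and 428. The lean of the control calls towards LDX thus turned in both settings. Without LD control replicate 1 the control comparison gave 1050 calls. Sums over each pool gave 1330 (683 higher in LD, 647 in LDX), of which 995 were among the control and 1046 among the MAMP calls.

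By adjusted calls the RILs differed from each other in fewer transcripts than the parents, though at an unadjusted p under 0.05 (edgeR) the control counts were 5253 and 5060. In control libraries 288 were higher in R-11268 and 364 higher in R-11272 (652 calls), and in MAMP libraries 221 and 389 (610 calls). Chromosome 18 again had the highest share, with 83 of its tested transcripts called in control libraries (4.47%) against 1.95% over all chromosomes. Of the 652 control calls, 342 were also called between the parents, against 34.2 expected if the lists were independent. Both lists use the same spread per transcript, so they are not independent and part of that excess is built in. Glyma02g03230.1 was present in R-11268 (4040 ± 760 CPM), as in LD, and nearly absent in R-11272 (1.18 ± 0.803 CPM), as in LDX (SD, n = 3), a ratio of 3920 (2940 to 5320; edgeR adjusted p = 1.87e-09). Its neighbour by number, Glyma02g03220.1, had 656.9 estimated counts in R-11268 controls and 0 in those of R-11272, at least 185-fold higher (edgeR adjusted p = 1.43e-06). Glyma18g35940.1 had 2132 estimated counts in R-11272 and 0.994 in R-11268, a ratio of 2540 (453 to 99900; edgeR adjusted p = 8.95e-11). Glyma20g23500.1 had 628 in R-11272 and 0 in R-11268, at least 248-fold lower in R-11268 (edgeR adjusted p = 0.0171; 5 of 14 alternatives ended this call). Without the 3 pools apart 1306 transcripts were called in control (670 higher in R-11268, 636 in R-11272) and 1406 in MAMP libraries, and with only the 6 libraries compared 162 (91 and 71) and 235. Sums over each pool gave 435 (195 and 240), of which 285 were among the control and 311 among the MAMP calls. The lean of the control calls towards R-11272 turned without the 3 pools and on the compared libraries, and also at a mean of 100 estimated counts (56 and 36). Leaving out any R-11268 control library, or R-11272 control replicate 1, brought the control count to between 352 and 397, with more calls higher in R-11268 each time (189 and 163 without R-11272 control replicate 1), and leaving out any R-11268 MAMP library brought the MAMP count to between 361 and 381.

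The study's design asks how differences between parents pass to their descendants, and expression can be described in the same way. Of the transcripts that differed between LD and LDX, 1118 could be placed. In R-11268, 335 were LD-like, 349 LDX-like, 382 between and 52 outside the parental range. In R-11272, 306 were LD-like, 470 LDX-like, 246 between and 96 outside. With a mean of 100 or more estimated counts, 2 of 237 were outside in R-11268 and 5 in R-11272. The class is thus mainly one of scarcer transcripts and is not read as expression beyond the parents. Among classed transcripts (LD-like or LDX-like) the LD-like share was 49% in R-11268 and 39.4% in R-11272. With between and outside transcripts left out, these classes ran in blocks along chromosomes. In R-11268, 453 of 657 neighbouring pairs (68.9%) had the same class against 59.2% on average in shuffles within chromosomes (permutation p = 1e-05, the smallest that 100000 shuffles give), and in R-11272 545 of 750 (72.7%) against 58.1% (permutation p = 1e-05).

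Chromosome 18 serves as an example, with runs counted over LD-like and LDX-like loci only. R-11268 had 92 LDX-like and 5 LD-like loci there, with runs of 43 LDX-like loci from number 5070 to 41280 and of 37 from 41620 to 50970. R-11272 had 37 LD-like and 47 LDX-like loci, with a run of 16 LD-like loci from 7260 to 10610 and a run of 32 LDX-like loci from 43490 to 52260. The run of 32 was longer than any in 10000 shuffles within chromosomes (highest 29, permutation p = 1e-04, the smallest they can give), while that of 43 in R-11268 was not (permutation p = 0.3), since nearly all classed loci of that chromosome were LDX-like. On chromosome 19 R-11268 had 21 LD-like and 6 LDX-like loci and R-11272 6 and 21. On chromosome 15 R-11272 had 33 LD-like and 9 LDX-like loci, and on chromosome 20 R-11268 had 45 LD-like and 11 LDX-like loci.

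**Figure D3:**
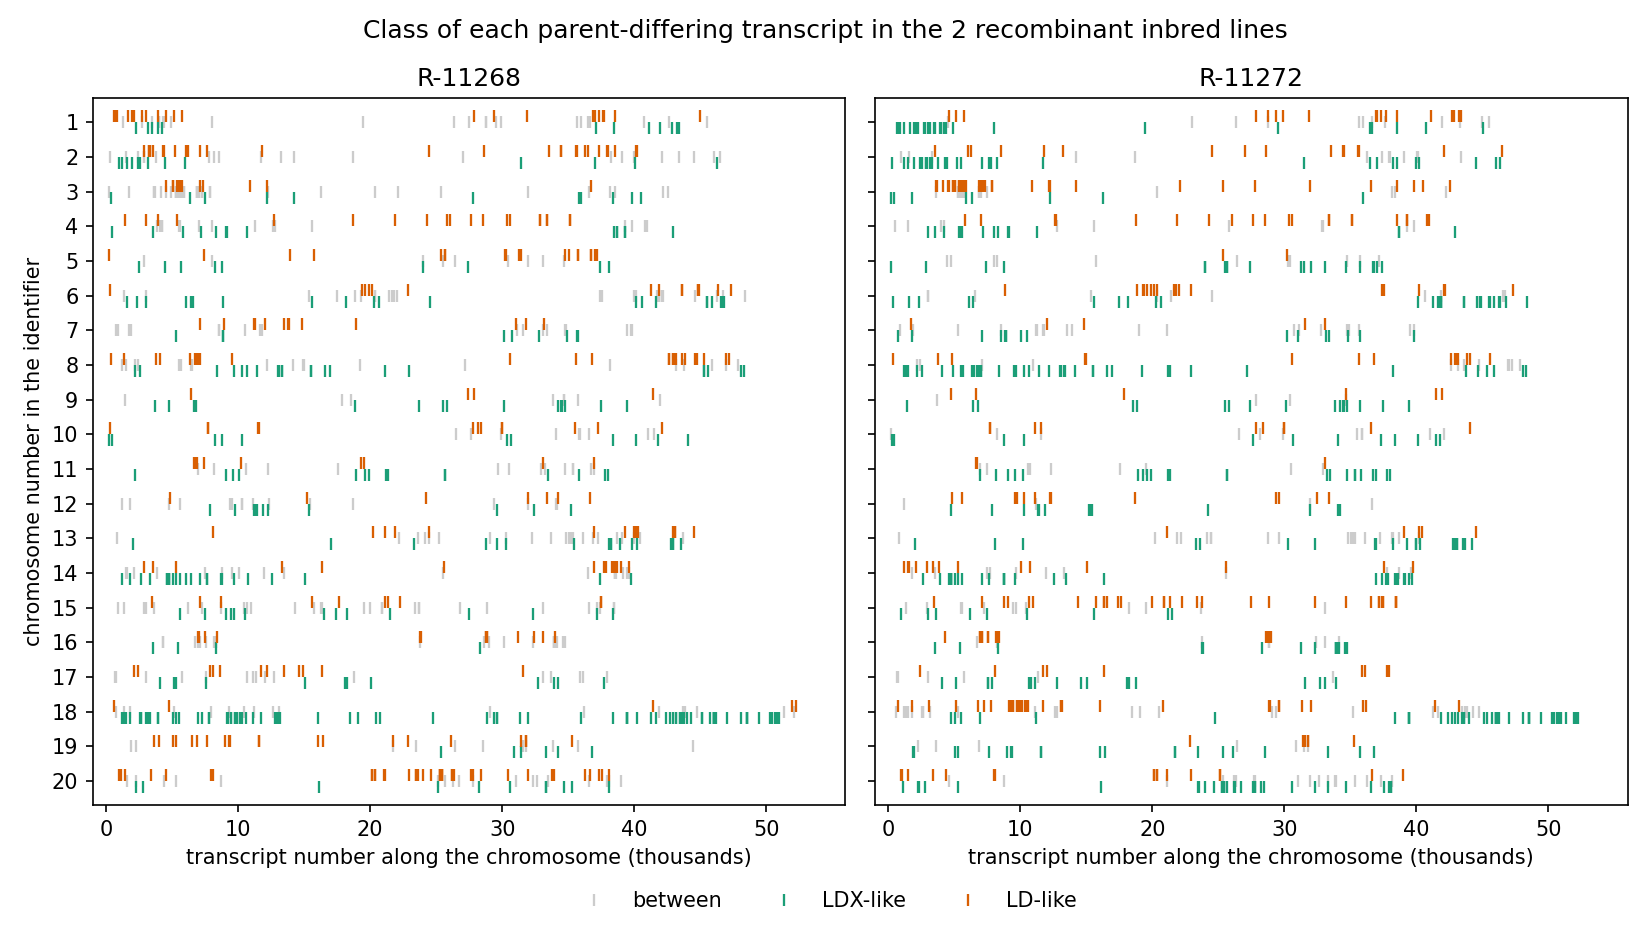
Parent-differing transcripts of R-11268 (left) and R-11272 (right), drawn by chromosome (vertical axis) and by the number in the identifier divided by 1000 (horizontal axis); each tick is 1 transcript, coloured and offset by its class from 3 MAMP libraries per line, and the outside class is not drawn. R-11268 has 92 LDX-like and 5 LD-like loci on chromosome 18, and R-11272 37 LD-like and 47 LDX-like ones.

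The block structure held for transcripts chosen in MAMP and placed in control libraries (72.5% in R-11268, 71.5% in R-11272). Choice and placement are not independent. The choice also required a parental difference of at least 0.5 in the libraries used for placement, and both steps use the same plant pools. The LD-like share of R-11268 did not hold a fixed value: it was 61.9% in that setting and 40.4% without the 3 pools apart.

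Of the 12 plant pools, 3 stood apart from the other pools of their line, namely LD pool 2, LDX pool 3 and R-11272 pool 1. A first component of pool deviations from line means carried 74.2% of their variance, and scored 67.8, 155 and 146 for these pools against -94.6 (R-11272 pool 3) to 12.7 for the others. LD pool 2 is the mildest of the 3: its root mean square deviation from its line mean was 0.486, below the 0.593 of LDX pool 1 and the 0.549 of R-11272 pool 3, against 0.871 in LDX pool 3 and 0.831 in R-11272 pool 1. The 10 most abundant transcripts took 8.19% of the counts in LDX pool 3 and 12.2% in R-11272 pool 1, against 4.43% to 6.01% in the other pools of these lines and 4.75% in LD pool 2. They had the lowest pool totals of their lines, with 24.1, 28.9 and 29.1 M estimated counts. No pool of R-11268 stood apart in this way.

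**Figure D4:**
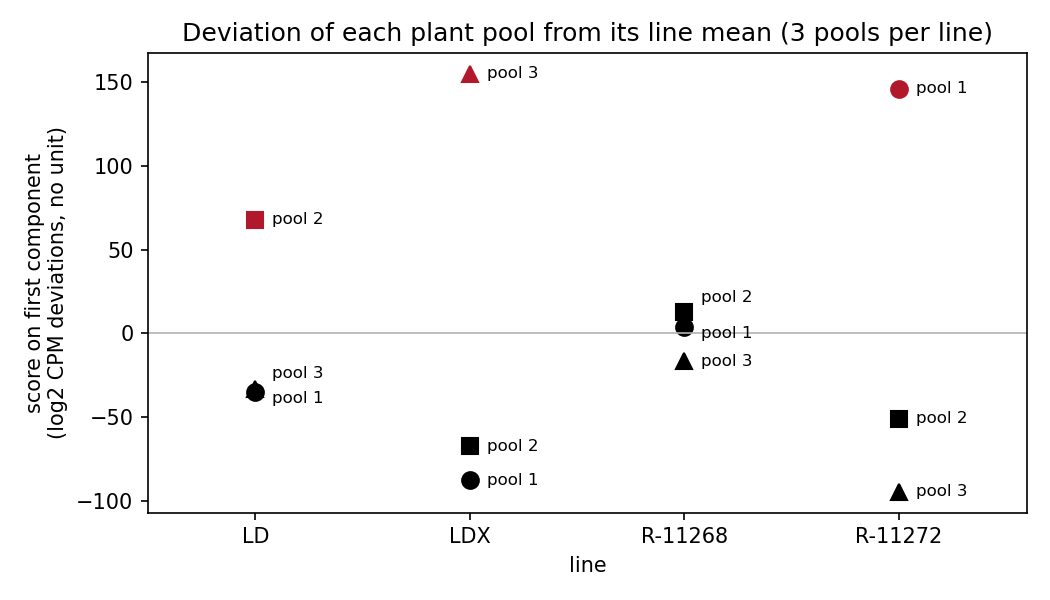
Score of each plant pool on the first component of log2 CPM deviations from line means (vertical axis, no unit) by line (horizontal axis); marker shapes give the pool number, and each point sums the control and MAMP library of 1 pool. The 3 pools in red score 67.8, 155 and 146, and the other 9 score from -94.6 to 12.7.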

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

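All tests of the grouping in this part were written down after the counts had been seen. The size of the MAMP response differed between lines in tests of the difference itself. The F test over the 4 lines called 49 transcripts, the test of LD minus LDX called 4 and that of R-11268 minus R-11272 called 11. The single transcripts named for this had differences of 2.39 (Glyma17g05240.1) and 3.20 (Glyma08g07080.1) between the parents and of 2.84 (Glyma14g21580.1), -4.30 (Glyma03g41580.1) and -2.51 (Glyma20g25110.1) between the RILs, on the log2 scale. At an unadjusted p under 0.05 the same edgeR tests gave 1317, 933 and 968 of 33214 transcripts. Plant pools were reassigned to lines in 50 ways, and 1 of the 50, the real one, gave as many calls as the 49 of the F test, while the highest of the others gave 1. These splits cannot decide whether chance gave the calls. The deposited values were fitted with the real labels, which leaves no scatter of the response within a real line, so the real grouping was favoured from the start. Simulated fitted values without any difference of responses gave 0 calls in the F test (edgeR) but 518 transcripts at an unadjusted p under 0.05, against 69 before fitting. These simulations did not copy the small scatter of scarce transcripts in the deposited table, so the 0 calls do not settle the matter.

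For the tests of 3 against 3 libraries or pools there are 10 splits, so no share under 0.1 can be reached. In each of them 1 of the 10 splits, the real one, gave as many calls and the highest other gave 0. The real counts were 1551 for the response in LD, 1254 in LDX, 1125 in R-11268 and 1429 in R-11272, then 1741 and 2126 for LD against LDX in control and MAMP libraries, 652 and 610 for R-11268 against R-11272, and 4 and 11 for the 2 response differences. Swapping treatments between libraries within lines gave 3238 calls or more for the mean response in 2 of 50 splits, the real one included, a share of 4%. The other split called 5124 transcripts, which points to a structure of the samples. It parted 8 of the 12 pools and put 5 of the 6 libraries of the 3 pools that stand apart on the control side. Other splits with the same imbalance of these libraries called 0, so the imbalance alone does not account for it. Of the drawn splits 1 other parted all 12 pools, as the real one does, and it called 0. As above, the real labels shaped the fitted values, so none of the splits of a MAMP response can decide about chance.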

How the results depend on the processing

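The upward lean of the MAMP response and the blocks of parental classes kept their direction in every alternative run, except in the void blocked fits. The size of that lean depended on the pools. Without the 3 pools apart, falls in the mean response came much closer to rises in number. No named transcript changed sign. The balance of the line differences did turn. Of the control calls between LD and LDX 45.2% were higher in LD, against 58.9% without the 3 pools apart, 56.3% on the compared libraries, and 52.2% and 50.2% without LD control 3 or LDX control 3; summed pools gave 51.4%. Of those between the RILs 44.2% were higher in R-11268, against 60.9% at a mean of 100, 56.2% on the compared libraries, 51.3% without the 3 pools, and 52.8%, 53.7%, 57.4% and 53.7% without R-11268 control 1, 2 or 3 or R-11272 control 1. In MAMP libraries the RIL balance turned at a mean of 100 (36.2% to 50.7%). The depth limits scarce transcripts, and a fitted table cannot show replicate error of a MAMP effect. DESeq2, its size factors and 2 other filters left most counts within 1.5 times. The exceptions were the 49 calls of the F test and the 4 of LD minus LDX, which became 77 and 7 with no filter, and 2 (DESeq2 size factors) and 8 (DESeq2) for LD minus LDX.

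With the replicate block, which pairs libraries by number, the calls were 18199 for the mean response, 14644, 13640, 11327 and 15709 in LD, LDX, R-11268 and R-11272, 17862 for the F test, 8682 for LD minus LDX and 10250 for R-11268 minus R-11272. These are void: simulated fitted values with no effect gave 14031. It changed no count of a line comparison by over 1.5 times.

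Some alternatives moved more, namely 3 chosen after seeing the data (a mean of 100, leaving out 3 pools, summed pools) and the planned fits on the compared libraries alone. With a mean of 100 or more estimated counts, which tests fewer transcripts, the calls were 1891 for the mean, 998, 759, 731 and 832 in the 4 lines, 8, 0 and 0 for the response differences, 430 and 574 for LD against LDX in control and MAMP libraries and 92 and 75 for the RILs; the edgeR tests with 0 calls had 4 and 11 before the filter. Without the 3 pools apart they were 6093, then 2446, 2165, 2743 and 3157, then 142, 0 and 31, then 4416, 4764, 1306 and 1406. Summing each pool gave 1330 for LD against LDX, MAMP. On the compared libraries alone, calls were 155 (LDX), 2546 (R-11268), 685 (R-11272), 0 (LD minus LDX), 382 and 428 (LD against LDX), and 162 and 235 (RILs). The cause was not tested for any of these beyond the change in transcripts or libraries used.

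Of the parental differences, 1118 transcripts became 562 at an absolute log2 fold of 2 or more, 237 at the mean of 100 and 2042 without the 3 pools. The LD-like share of R-11268 was 61.9% with treatments exchanged, 56.3% at log2 2 and 40.4% without the 3 pools. For R-11272 it was 49.1% at log2 2, 34.9% at the mean of 100 and 28.8% without the 3 pools.

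Leaving out 1 library at a time gave 2903 to 3407 calls for the mean response, 1159 to 1353 in LD, 870 to 1320 in LDX, 812 to 957 in R-11268, 1047 to 1501 in R-11272, 26 to 48 for the F test, 0 to 3 for LD minus LDX and 3 to 9 for R-11268 minus R-11272. It gave 1050 to 1572 and 1290 to 1914 for LD against LDX in control and MAMP libraries, and 352 to 558 and 361 to 457 for the RILs. The parental set held 808 to 1159 transcripts, same-class neighbours 68.5% to 74.7% and 71.7% to 75.3%, and LD-like shares 43.4% to 56.6% and 36.6% to 43.3% (R-11268, R-11272). LD MAMP replicates 1 and 2 moved the parental MAMP count to 1303 and 1290, and LD control 1, LD control 3 and R-11272 control 2 moved the F test to 32, 29 and 26. A left-out library still shaped the fitted values of the others. For named transcripts, 259 of 336 values kept their call, 77 lost it and 0 changed sign; these include the void blocked fits and leave out filters that removed the transcript. The pseudocount and quantile alternatives, meant for normalized values, and the gene lists were not run.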

Other observations

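Apart from 1 test of pool deviations, named below, the tests in this part were chosen after the pattern had been seen. Some transcripts were present in all 6 libraries of a parent (30 estimated counts or more in each) and absent in all 6 of the other (under 1 in each). There were 25 such transcripts present in LD, on 11 chromosomes, and 7 present in LDX, on 5 chromosomes. Of the 25, 15 were present and 4 absent in R-11268, and 17 were present and 4 absent in R-11272; the rest were low. By the same limits, 0 transcripts were present in a RIL and absent in both parents, and 0 were absent in a RIL and present in both. The RILs parted, with presence in 1 and absence in the other, at 3 of the 25 and 3 of the 7. Glyma02g03220.1, for example, was present in R-11268 alone, and Glyma18g09730.1 (chosen after its values were seen) in R-11272 alone.

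The RILs differed from each other at a higher rate where they carry different parental classes, which fits inheritance in segments as a hypothesis. For each locus the 3 classed transcripts before and the 3 after it were read, leaving the locus itself out, and a flank was assigned where at least 5 of the 6 were of 1 parent. Where the flanks of the RILs were of different parents, 134 of 2909 loci (4.61%) were called between the RILs in control libraries, against 50 of 4839 (1.03%) where both flanks were of the same parent. The ratio of 4.46 exceeded that of nearly all of 10000 rotations of the calls along the genome (95th percentile 1.84, permutation p = 0.0022). Of 97 such calls that also differed between the parents, 96 had the direction of the flanking parents. Most of the 652 calls lie elsewhere, among the 25279 loci with mixed or too few flanks. These calls were made on the same pools as the classes.

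Transcripts that rose with MAMP lay next to each other more often than by chance. Among 33027 loci, 1518 rose by 2-fold or more, and these formed 281 adjacent pairs against 69.6 in shuffles within chromosomes (highest of 10000 shuffles 96, permutation p = 1e-04, the smallest they can give). Of the 1518, 484 had a rising neighbour. A candidate explanation is that neighbouring genes, such as tandem copies, respond together. Reads shared between near-identical copies could add to this. Full sharing would give both members equal responses, and the median absolute difference within pairs was 0.585 on the log2 scale, against 0.876 for random rising pairs, with 15.7% of pairs within 0.1. Partial sharing cannot be told apart, since transcript sequences were not used here.

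In R-11268 some plants of a pool may have carried other parental segments than the rest. Glyma12g12280.1 and Glyma12g25730.1 (chosen after their values were seen), which LDX lacks, had 55.4 and 39.4 estimated counts in pool 2 of R-11268 and under 1 in pools 1 and 3, at 34.7% and 49.1% of the LD level. Such patterns are not peculiar to this line. With a pool total of 20 or more in 1 pool and under 1 in another, there were 10 transcripts in LD, 33 in LDX, 11 in R-11268 and 22 in R-11272, and of the 11 this pair had a total of 100 or more in LD and under 1 in LDX. Of the 22 in R-11272, 0 had such totals. In LD, LDX and R-11272 most were present in the pool that stands apart (LD pool 2, LDX pool 3, R-11272 pool 1). A weaker case is Glyma17g12610.1 on chromosome 17 (chosen after its values were seen), with totals of 58.9 in LD and 0.708 in LDX and 20.1, 3.92 and 0.767 in pools 1, 2 and 3 of R-11268. The parents show such patterns too, so they need no segregation. Most of the parental ones lie in pools that stand apart, and R-11268 has no such pool, so this is not a like comparison. LD material mixed into that pool is argued against, because 12 other LD-only transcripts by these limits, off chromosome 12, that pools 1 and 3 lack (under 2 estimated counts) reached at most 0.705% of the LD level there. A test written before its result was seen asked whether pool deviations point the same way at neighbouring parent-differing loci. The mean cosine over 195 pairs in R-11268 was 0.0472, under the 95th percentile of shuffles (0.0911, permutation p = 0.22), and that of the other lines was 0.0169 in LD, 0.115 in LDX and 0.0202 in R-11272. The shortfall is smaller than the SD of the shuffles (0.0508), and 1 segment would be diluted among 20 chromosomes, so segregating segments stay open, as a hypothesis only.

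The 3 pools that stand apart deviate in the same direction. Across 33214 transcripts the deviations of LDX pool 3 and R-11272 pool 1 correlated at 0.903, those of LDX pool 3 and LD pool 2 at 0.744 and those of R-11272 pool 1 and LD pool 2 at 0.628. The correlation of LDX pool 3 and R-11272 pool 1 was 0.897 after thinning every pool to 24056092 counts. Unequal totals in the table thus do not account for it. Thinning fitted values cannot undo what lower depth did before or in the authors' fit, so the part of depth itself is not settled. The part of a few abundant transcripts was not settled: without the 100 most abundant, which took 15.3% of counts, the root mean square deviation was 0.75 against 0.749, but this measure weighs all transcripts alike and could hardly move. A difference between batches of plants or libraries and a shared state of the plants cannot be told apart, because no label records a day or batch; the component carries 74.2% of the variance of pool deviations. The pools carry different numbers in their lines. The control and MAMP libraries of a pool move together, but the fitted values force this. It therefore does not show whether the deviation arose before or after treatment.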
